A study of Rattus norvegicus with 8 samples.

How the data were processed

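Reduced representation bisulfite libraries were made from hippocampal DNA of 8 rats, 4 with sham surgery and 4 with fluid percussion injury. Per the labels' protocols, DNA was digested with MspI, end-repaired, ligated to adapters, selected for short fragments, treated with bisulfite and sequenced on an Illumina HiSeq instrument. Bisulfite turns unmethylated cytosine into uracil, which is read as thymine. Per the submitters' processing notes, reads were aligned with Bowtie to the rn5 build; the version, the methylation caller, trimming and the treatment of PCR duplicates are not given in the sources used here. The deposited file of each animal lists cytosines with their strand and context, the count of methylated reads, the count of all reads, and their ratio as a deposited fraction. The counts were used, and the fraction served only to check them. Every listed cytosine has at least 10 reads, and the highest depth in each file is 8003 to 8021 reads, so depth may have been limited near that value. Reads from RRBS carry no molecular identifiers here, so counts may include copies of the same molecule, and intervals that rest on counts cover counting error only. A cytosine converted incompletely is read as methylated, 5-hydroxymethylcytosine cannot be told from 5-methylcytosine by this method, and a sequence variant that removes a CpG reads as an unmethylated or missing CpG. End repair can also add unmethylated cytosine at the MspI ends.

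Cytosines with an unclear context (4 to 6 per file) were left out. Reads of both strands of a CpG were added. A CpG was tested when all 8 animals had at least 10 reads, which left 901631 of the 1342101 CpGs listed in any animal on the nuclear chromosomes. CpGs of 1 tile of 200 bp were added per animal where at least 2 passed, giving a median of 3 CpGs and 128 reads per region and animal. A median depth of 38 reads per CpG gives coarse levels at single CpGs and finer ones in regions. Samples were grouped by the treatment named in the labels, and replicate numbers come from the titles. The labels list the samples as separate replicates and do not name the animals, so it was taken that each is 1 animal. At 9196 autosomal CpGs with 20 or more reads whose levels ranged over 40 points, taken at most once per 200 bp, any 2 animals differed by 18.4 to 26.3 points on average, so no library appeared to be a copy of another.

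The level of an animal is the methylated reads over all reads of the sites in a class. Group means of such levels were compared by an exact two-sided permutation test over the 70 assignments of 8 animals, and the 95% interval holds the shifts that this test did not reject. Regions, CpGs and 100 kb windows of CA cytosines (at least 50 cytosines per window) were tested with a quasi-binomial logistic model on counts, with group as the only term, overdispersion shrunken across features by the method of limma's squeezeVar with a floor of 1, an F test and Benjamini-Hochberg adjustment. A call needs an adjusted p below 0.05 and, for CpGs and regions, a difference of at least 10 points between pooled levels. The alternatives included edgeR's quasi-likelihood test on methylated and unmethylated counts, limma on logit levels with 0.5 added to both counts, Fisher's exact test on pooled reads, 20 reads in every animal, sites outside listed CCG and CGG, other region widths, the replicate number as a block, and each animal left out in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and limma 3.58.1 were used.

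The tests were tested on simulated counts drawn at the real levels and depths, with 200 features of middle level changed at each size. Overdispersion was drawn for each feature from the fitted prior, not taken from the feature itself. Each feature was drawn on its own, so differences between animals that many features share were not simulated. The quasi-binomial test gave an unadjusted p below 0.05 for 6.14% of unchanged CpGs, 5.56% of unchanged regions and 4.95% of unchanged windows. Its unadjusted p was thus slightly liberal for CpGs and regions in the simulation. In the real data the shares were lower, at 5.16% of CpGs, 4.29% of regions and 2.19% of windows, so the simulated rates need not hold there. It recovered 25.5, 77.0, 96.5 and 100% of CpGs changed by 20, 30, 40 and 50 points, with 117 false calls beside the planted changes, and limma on logit levels recovered 0, 1.0, 39.0 and 87.0% with 6 false calls. Beside the 51, 154, 193 and 200 CpGs that the quasi-binomial test recovered, its 117 false calls were a larger share than the adjusted threshold of 0.05 allows. Its adjusted CpG calls were thus not held at that rate in the simulation. Among regions the quasi-binomial test made 23 false calls. Planted changes loosen the adjusted threshold, so these counts are not those expected where nothing changed. For the same reason the recovered shares are higher than where few features change. The prior of the fit with the replicate number as a block was refitted on features with reads of both kinds after the simulation showed that it recovered nothing otherwise.

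The features named in the text were chosen by a rule set before the data were examined. It took called regions with the largest difference (up to 12 per direction), the 5 regions with the smallest p in a direction with fewer than 5 calls, and up to 5 called CpGs per direction with another called CpG of the same direction within 200 bp. The CpG at 20:54160521 has the largest difference and was singled out after its values were seen, as were single CpGs inside the named regions and the CpG at 109931032. Results planned for promoters, gene lists and gene bodies were not run, because the reference at hand is a gene table of the GRCr8 build, which shares no coordinates with rn5. CA methylation was tested in windows instead, a choice made after the data were seen. The class of a region was its CpG density only. The planned minimum of 5 reads could not be run, since the files start at 10 reads.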

Results

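Genomic DNA from the hippocampus of 8 male Sprague-Dawley rats, an outbred stock, was measured by reduced representation bisulfite sequencing, which reads cytosine methylation in DNA fragments that end at MspI sites and so favours CpG-rich sequence. In 4 animals a traumatic brain injury (TBI) had been made by fluid percussion, a pressure pulse applied to the exposed dura, and 4 animals had sham surgery. The tissue was taken 1 week after surgery, when the animals had also been tested for learning. Each animal gave between 8655904 and 9942994 cytosines, every one with at least 10 reads, and the read counts over these cytosines summed to between 288418418 (TBI 1) and 334496610 (sham 1). At the 901631 CpGs of the nuclear chromosomes with 10 or more reads in all 8 animals the median depth was 38 reads per CpG and animal, and the median of single animals lay between 35 and 40. All positions are given in the rn5 build. No gene annotation of that build was used here, so regions are named by position and not by gene.

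The first comparison asked whether the injury changed the overall level of CpG methylation in the hippocampus. CpG methylation was 45.9% ± 0.669 (SD, n = 4) in sham animals and 46.3% ± 0.578 (n = 4) in injured animals. The difference of 0.429 percentage points was smaller than the spread between animals of either group (95% interval -0.763 to 2.08; exact two-sided permutation test, p = 0.314, where the smallest p the design allows is 0.0286). The lowest animal was sham 3 at 44.9% and the highest was TBI 1 at 47.0%. The difference was 0.0947 points without sham 3, 0.208 without TBI 1 and 0.682 without TBI 3. With each site counted once, whatever its reads, it was 0.163 points. On the X chromosome, present in 1 copy in these males, 15164 CpGs had a level of 52.8% ± 0.292 in sham and 53.1% ± 0.701 in injured animals, a difference of 0.354 points (exact permutation p = 0.4). By the mean level over all 8 animals, 36.6% of CpGs stood under 10%, 23.0% at 90% or more, and 40.4% between.

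Methylation outside CpGs was examined next, because methylation at CA is a known feature of adult neurons while CC and mitochondrial cytosines are rarely methylated and mainly carry the bases that escaped conversion. The level at 2138620 CA cytosines was 1.34% ± 0.143 in sham and 1.28% ± 0.145 in injured animals (n = 4 each), a difference of -0.0521 points with a 95% interval of -0.407 to 0.209 (exact two-sided permutation test, p = 0.629). Within CA the level was higher at CAH, where H is any base but G, than at CAG. It was 1.55% ± 0.171 in sham and 1.49% ± 0.177 in injured animals at CAH, and 0.982% ± 0.097 and 0.952% ± 0.0938 at CAG. CT cytosines had 0.563% ± 0.0435 and 0.546% ± 0.0446. The background levels were 0.311% ± 0.00432 and 0.307% ± 0.00414 at CC, and 0.246% ± 0.0184 and 0.251% ± 0.0106 at 50 mitochondrial cytosines. None of the 8 contexts tested passed the test for a group difference (exact permutation tests, Benjamini-Hochberg adjusted p = 0.714 for each). Single animals spanned 1.14% (TBI 1) to 1.54% (sham 1) at CA, a 1.36-fold range over the 8 animals, with 1.22 to 1.54% among sham and 1.14 to 1.43% among injured animals. The sign of the group difference rested on 1 animal, since without sham 1 it was 0.0174 points. It was -0.00308 points without TBI 1, -0.0187 without TBI 3, -0.0870 without TBI 4, -0.0913 without sham 2 and -0.100 without TBI 2.

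**Figure D1:**
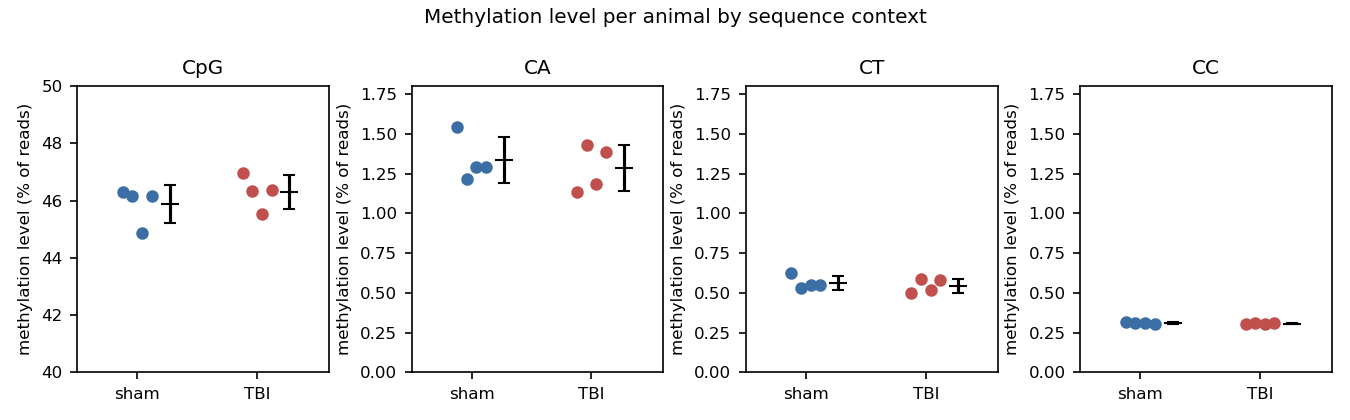
Methylation level in percent of reads (vertical axis) for each animal, by group, at CpG, CA, CT and CC cytosines; points are animals and the bars give the mean and SD of 4 animals. The CpG axis runs from 40 to 50% and the other axes start at 0. CpG levels lie between 44.9 and 47.0%, CA levels between 1.14 and 1.54%, and the groups overlap in every context.

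Whether a difference was tied to a class of sequence was asked by sorting 183660 regions of 200 bp by the number of CpGs measured in them. Regions with 2 to 3 CpGs were the most methylated, at 68.2% ± 0.667 in sham and 68.5% ± 0.611 in injured animals. The level fell with CpG density through 58.1% ± 0.652 and 58.5% ± 0.654 at 4 to 6 CpGs and 31.3% ± 0.683 and 31.8% ± 0.438 at 7 to 10 CpGs. Regions with 11 to 15 CpGs stood at 8.05% ± 0.185 and 8.17% ± 0.193, and the densest class, with 16 or more CpGs, at 2.26% ± 0.375 and 2.46% ± 0.503. The injured group was higher in each of the 5 classes by 0.121 to 0.514 points, and no class passed the test (exact permutation tests, adjusted p = 0.543 in all 5, n = 4 per group). Classes share animals, so their differences are not independent of one another. With any animal but sham 4 left out, at least 1 class difference moved by over 1.5 times. Without sham 3 the classes differed by 0.0213 to 0.18 points, without TBI 3 by 0.206 to 0.737 points, and the densest class differed by 0.0102 points without TBI 2 and by 0.381 points without TBI 1.

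**Figure D2:**
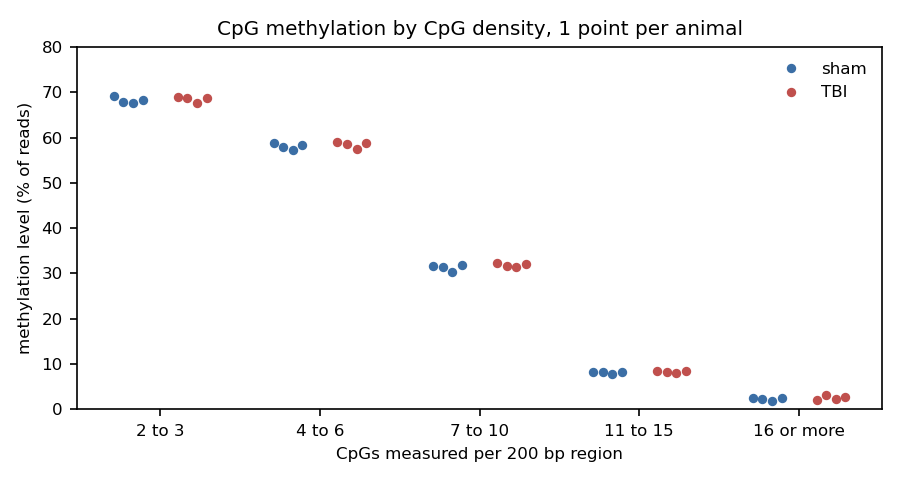
CpG methylation level in percent of reads (vertical axis) against the number of CpGs measured per 200 bp region (horizontal axis), with 1 point per animal. The level fell from about 68.2% at 2 to 3 CpGs to 2.26% at 16 or more CpGs in sham animals, and the levels of the groups overlapped in each class.

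Regions of 200 bp were then tested one by one for a difference between injured and sham animals. Of 182845 regions, 1 was called at an adjusted p below 0.05 with a difference of at least 10 points (quasi-binomial test, Benjamini-Hochberg adjustment), and it was lower after injury. This region, on chromosome 11 from 20476744 to 20476795, holds 3 CpGs and had a level of 96.2% ± 0.717 in sham and 78.2% ± 3.12 in injured animals (adjusted p = 0.014, 166 to 234 reads per animal, lower in 4 of 4 injured animals). The difference lay in a single CpG at 20476795, which stood at 91.4 to 100% in sham and 39.1 to 56.1% in injured animals (adjusted p = 9.53e-07), while the CpG at 20476767 had 97.9% and 97.0%. That CpG lies in a CCG or CGG, and with such CpGs left out the region differed by 0.130 points. The call was also lost with limma on logit levels (adjusted p = 0.171) and without sham 2, sham 4 or TBI 2 (adjusted p = 0.063, 0.102 and 0.0993). With the replicate number as a block this region was not called either. Over all its 22 alternatives the adjusted p ranged from 6.72e-25, by Fisher's test on pooled reads, to 1.0.

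A second region, on chromosome 1 from 154948963 to 154948972, had an adjusted p of 0.0195 but a difference under the minimum size: in pooled reads it fell by 8.95 points, and the mean of the animals went from 72.5% ± 1.44 to 63.9% ± 1.24. It had 75 reads in sham 3 and 2108 to 3668 in the other animals. The remaining regions named by the rule fixed in advance did not pass the test. Among those with higher levels after injury, a region of 7 CpGs on chromosome 2 (114286411 to 114286533) had 15.4% ± 1.73 in sham and 31.1% ± 5.08 in injured animals, with all 7 CpGs higher in the injured group's mean (adjusted p = 0.499, 161 to 246 reads). A region of 5 CpGs on chromosome 7 (2933681 to 2933755) had 71.2% ± 12.4 and 93.3% ± 1.78 (adjusted p = 0.392), and without sham 2, the sham animal at 88.6%, its adjusted p was 0.0126 (range over its alternatives 6.58e-43 to 1.0). Sham 1, sham 3 and sham 4 had 279 to 394 reads there, against 185 in sham 2 and 210 to 245 in injured animals. On chromosome 3 (174233215 to 174233366, 10 CpGs) the levels were 82.9% ± 3.99 and 93.7% ± 0.524 (adjusted p = 0.346). In that region the CpG at 174233273 carried the difference, with a mean of 32.9% in sham and 91.8% in injured animals, and the mean of each of the other 9 differed by less than 6 points. On chromosome 20 (54160521 to 54160546, 3 CpGs) the levels were 72.6% ± 2.09 and 90.7% ± 3.61, and on chromosome 15 (86930291 to 86930342, 3 CpGs) they were 53.7% ± 7.36 and 73.4% ± 1.47 (adjusted p = 0.499 for both). In the latter the CpG at 86930342 carried the difference, with means of 27.9% and 66.9% and with 0% in sham 3. Among those with lower levels, the region at 48326898 to 48326973 on chromosome 15 had 95.8% ± 2.06 and 78.6% ± 6.51 (adjusted p = 0.346). On chromosome 1, the region at 192126860 to 192126870 had 83.2% ± 1.28 and 53.1% ± 10.3 (adjusted p = 0.499) and the region at 193405296 to 193405394 had 93.0% ± 2.32 and 73.1% ± 8.09 (adjusted p = 0.66). In these 3 regions 1 CpG carried the difference: the sham and injured means were 95.7% and 33.9% at 48326963, 89.1% and 14.5% at 192126860, and 96.1% and 20.7% at 193405352. The other CpG of the region at 192126860 went the opposite way, from 77.4% to 90.9%. The regions at 192126860 and 193405296 passed without TBI 4 (adjusted p = 0.0312 and 0.0306; over their alternatives the lowest were 6.19e-13 and 1.59e-20, by Fisher's test, and the highest 1.0). Over all regions the difference had a median of 0.0309 points, and 4.29% of regions had an unadjusted p below 0.05. On simulated data of the same depth, the test recovered 51.0% of regions changed by 20 points and 84.5% of those changed by 30 points. There, 200 regions of middle level were changed at each size, which loosens the adjusted threshold. Recovery is therefore lower where few regions change, and regions of other levels were not changed in the simulation. The enrichment of called regions in a density or level class was not informative with 1 call (smallest adjusted p = 1.0 by Fisher's exact test).

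**Figure D3:**
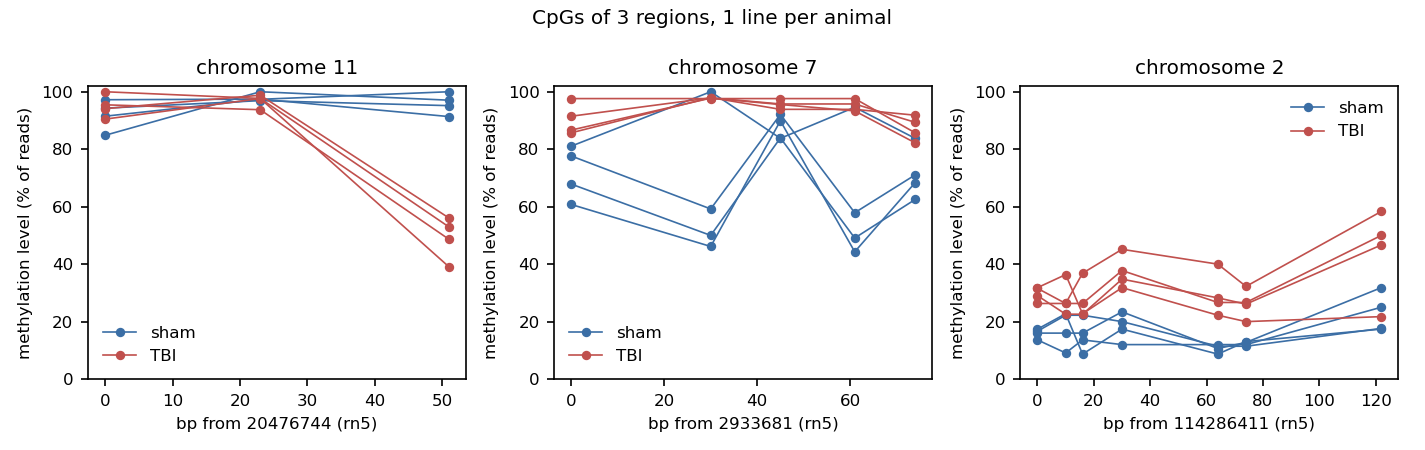
Methylation level in percent of reads (vertical axis) of each CpG in 3 regions against its distance in bp from the first CpG (horizontal axis, rn5), with 1 line per animal in the group's colour. On chromosome 11 only the last CpG separates the groups, at 39.1 to 56.1% after injury. On chromosome 7, sham 2 had the highest sham level over the region, 88.6%, and on chromosome 2 the injured group's mean is higher at all 7 CpGs.

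At single CpGs, 120 of 804786 were called, 56 higher and 64 lower in injured animals, with a median difference of 40.8 points and a range of 13.5 to 75.7 points (quasi-binomial test, adjusted p below 0.05 and at least 10 points). They lay on 20 chromosomes. The smallest adjusted p, 9.53e-07, was that of the CpG in the called region on chromosome 11. The largest difference was at 54160521 on chromosome 20, with 0.962% in sham and 75.0% in injured animals, while the CpGs at 54160538 and 54160546 had means of 96.3 to 97.4% in both groups. For 101 called CpGs another CpG within 50 bp was measured. The median difference of these neighbours in the direction of the call, called ones included, was 2.35% of the called CpG's own. Moves the opposite way counted as negative. The number of calls depended on the test, with 2 by limma on logit levels, 918 by edgeR's quasi-likelihood test and 2493 by Fisher's test on pooled reads. With any 1 animal left out it was 242 to 460. It rose whichever animal was left out, so the rise does not point to particular animals.

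Calls with another called CpG of the same direction within 200 bp numbered 10. On chromosome 8, the CpGs at 109931032 and 109931041 rose from 40.3% ± 10.1 to 66.8% ± 7.66 and from 34.3% ± 12.5 to 63.1% ± 8.53 (adjusted p = 0.0358 and 0.033, 57 to 91 reads). There the 6 other CpGs within 100 bp were also higher in the injured group, by 14.0 to 19.4 points in pooled level, and none of these passed on its own. On chromosome 7, the CpGs at 2933711 and 2933742 rose from 63.8% ± 24.7 to 97.8% ± 0.146 and from 61.5% ± 22.8 to 95.1% ± 1.95 (adjusted p = 0.00137 and 0.00237), although sham 2 had 100 and 94.6%. Sham 1, sham 3 and sham 4, with the lower levels, had 55 to 79 reads at these 2 CpGs. Sham 2 had 37 and injured animals had 42 to 49, and why depth differed was not tested. The other 3 CpGs within 100 bp were higher by 7.32 to 19.6 points in pooled level. On the same chromosome, the CpG at 14132734 had 47.6% in sham 3, 95.5 to 100% in the other sham animals and 28.2% ± 1.35 in injured animals (adjusted p = 0.00278), and the CpG at 14132731 went from 90.1% ± 9.70 to 65.2% ± 3.15 (adjusted p = 0.0376). Depth went with the level at both: injured animals had 156 to 184 reads and sham 3 had 126, against 44 to 65 in the other sham animals. The lower levels thus came with more reads, and why depth differed was not tested. The 8 other CpGs within 100 bp differed by -10.7 to 3.09 points in pooled level. On chromosome 1, the CpGs at 191163947 and 191163939 had 2.92% ± 3.54 in sham and rose to 53.3% ± 28.0 and 43.9% ± 26.4 (adjusted p = 0.00611 and 0.0377, 14 to 37 reads), although TBI 4 had 14.3 and 7.14%. The 9 other CpGs around them did not separate the groups: sham 3 had 78.6 to 92.9% and sham 2 had 33.3 to 53.3% there, and none passed (lowest adjusted p = 0.757). The 7 of these CpGs named by rule, all but 109931032, kept their direction in all alternatives run for them, and none was called by limma (adjusted p of 0.751 to 0.985). The call at 109931041 was lost without sham 1, sham 3 or TBI 3 (adjusted p = 0.077, 0.0786 and 0.0542) and at 20 reads (0.0636). That at 14132731 was lost without sham 1 or sham 4 (0.0949 and 0.0733) and at 20 reads (0.0735). That at 191163939 was lost without sham 1, sham 2, sham 3, TBI 2 or TBI 3 (0.0583 to 0.095). By Fisher's test on pooled reads all 7 had far smaller values, from 2.46e-37 to 2.03e-07.

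CA methylation was also tested in 12549 windows of 100 kb. No window was called (quasi-binomial test, smallest adjusted p = 1.0), 275 windows (2.19%) had an unadjusted p below 0.05, and limma on logit levels called 1 window. The median window differed by -0.0446 points, and 36.8% of windows were higher in injured animals. On simulated data the test recovered 83.0, 47.0 and 7.5% of windows whose CA level was raised by 100, 50 and 25%, and 63.5% of those lowered by 50%. With 200 windows changed at each size the adjusted threshold is looser, so recovery is lower where few windows change. In the simulation 4.95% of unchanged windows had an unadjusted p below 0.05, against 2.19% of the real windows. The recovered shares therefore need not hold for the real windows.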

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

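The tests on neighbouring CpGs, on the splits of the animals by CpG and region calls, on conversion and on injury, and the correlations, were chosen after the results were seen. Of 68 groups of 4 animals examined, 7 had an animal whose gap to the nearest other, as a share of the group's range (the ratio below), exceeded Dixon's 95% critical value, against 3.4 expected by chance at 1 in 20. The groups share animals and sites, and the named features among them were chosen by their values. The 2 counts are therefore no test of an excess. In overall CpG methylation, sham 3 lay apart at 44.9% from 46.1 to 46.3% in the other sham animals (ratio 0.886), and on the autosomes alone at 44.8% (ratio 0.891). Without sham 3 the group difference was 0.0947 points. At CTG, sham 1 had 0.369% against 0.341 to 0.345% (ratio 0.86). In the region at 174233215 on chromosome 3, sham 2 had 76.9% against 84.6 to 85.3% (ratio 0.912). In the region at 154948963 on chromosome 1, TBI 4 had 65.7% against 63.2 to 63.5% (ratio 0.884). At the CpG at 14132734 on chromosome 7, sham 3 had 47.6% against 95.5 to 100% (ratio 0.913), and TBI 3 had 30.2% against 27.4 to 27.7% (ratio 0.883).

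The 120 called CpGs were first set against other ways to divide the animals. In 32 of the 35 splits of the 8 animals into 4 and 4, the real one included, as many CpGs were called, and the highest other split gave 397, so chance cannot be excluded. A change of the surrounding DNA with injury, in the direction of the call, is argued against for the calls as a set. The evidence is the neighbours within 50 bp, called ones included. Their median difference in the direction of the call was 2.35% of the call's own (95% bootstrap interval 1.24 to 5.26%). In 89 of 101 calls the neighbours moved in that direction by under 25% of the call's difference, or moved the opposite way. In 3 they moved in that direction by 50% or more. A change of the surrounding DNA stays open for these 3 and for the calls between those bounds. It also stays open for the calls with no other CpG measured within 50 bp. Neighbours that moved the opposite way were not counted apart. The same value, 2.35%, is consistent with sequence variants that remove or create a CpG in some animals, although an isolated error or chance would leave neighbours in place too. Among the calls, 51 pairs lay within 1 Mb, against a median of 9 and at most 31 in 10000 random lists of tested CpGs. The lists were not matched for range. Of the calls, 108 ranged 40 points or more, while 3.59% of tested CpGs ranged over 40 points. Pairs within 200 bp were counted too. The comparison thus cannot tell whether the calls cluster more than other widely ranging CpGs, and no genotypes were analysed here.

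For regions, 15 of the 35 splits gave as many calls as the real 1, and the highest other gave 5, so chance cannot be excluded. With 0 windows of CA methylation called, all 35 splits necessarily gave as many, so there was no call to weigh against chance. The highest other split gave 464 windows and also the 397 CpGs. It sets sham 2, sham 4, TBI 1 and TBI 3 (CA levels 1.22, 1.29, 1.14 and 1.18%) against the rest, at 1.29% (sham 3) to 1.54% (sham 1). That nearly sorts the animals by CA level, the quantity tested in the windows, so many called windows follow from the sorting. The split of sham 2, sham 3, TBI 1 and TBI 3 against the rest gave 201 windows. The CpGs of the highest split number 3.31 times the real count and the median of the other splits is 188.5, which may come from a structure of the animals apart from the injury. The highest split was picked for its size, and no test was made for the highest of 34.

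CA methylation differed 1.36-fold between animals. Incomplete conversion as the whole source would raise CC as much, and the CC range was 3.59% of the CA range. CC did rise with CA over the 8 animals (Pearson r = 0.831, adjusted p = 0.0395, and 0.696 without sham 1 and TBI 1). By rank this did not pass (Spearman correlation 0.690, adjusted p = 0.23). The mitochondrial level, the other background, did not rise with CA (Pearson r = -0.304, adjusted p = 0.53). A small share from conversion stays open. Sequencing depth would shrink the range at deeper sites, and at 20 or more reads it was 98.4% of the range at 10 or more. The total reads of an animal went with its CA level at r = 0.680 (adjusted p = 0.163), which rested on sham 1 and TBI 1, as r was -0.0378 without them. The depth test covers sites and not these totals, which stay open for those 2 animals. Injury as the source is argued against by the sham animals alone, whose range was 6.25 times the difference of the group means. Different shares of neuronal DNA in the dissected tissue remain open: 2600 regions had a CpG level that followed the CA level at p below 0.01, against a median of 1884.5 in 100 permutations of the CA levels, and 6 permutations gave as many. This lies between the bounds set beforehand, and neither cell counts nor cell-type marker genes were analysed here.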

How the results depend on the processing

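The settings without CpGs ranging over 40 points, with the CA level as covariate, and all of those for CA windows were chosen after seeing the data; the others were set before the data were examined. The cause of a change was not tested unless stated. Global CpG methylation and the 5 density classes kept their direction and side of the threshold under all alternatives run for them. Called CpGs (120) numbered 64 at 20 reads, where fewer sites were tested, 2493 with Fisher's test, which ignores the spread between animals, 2 with limma, 918 with edgeR, 182 with strands apart, 69 without CpGs ranging over 40 points, and 242 to 460 with 1 animal left out; 12 of those 69 were among the 120. The lowest count came without sham 2 and the highest without TBI 1, and each of the 8 animals left out raised it over 1.5 times. The called region (1) became 0 without CCG and CGG CpGs, with limma, at a 20-point minimum, with at least 5 CpGs and without CpGs ranging over 40 points. It became 2021 with Fisher's test, 2 with no minimum difference, and 0 to 8 with 1 animal left out: 0 without sham 4 or TBI 2, 4 without sham 1, 8 without TBI 4. Without sham 2 the 1 call was another region. Limma called 1 CA window where the main test called 0. The CA difference ranged from -0.1001 to 0.0174 points with 1 animal left out, turning only without sham 1. With regions at unadjusted p below 0.01, 11 of 18 tests of a class and a direction passed, 5 as over-represented and 6 as under-represented. Regions of mean level 20 to 80% were over-represented among higher and lower ones (odds ratios 2.64 and 1.84), as were those with 4 to 6 CpGs (1.42 and 1.55). Regions with 7 to 10 CpGs were so among higher ones only (1.36). Fisher's test takes regions as independent, though they share the animals, so these results do not tie a class to injury. The regions at unadjusted p below 0.01 were 0.719% of those tested, fewer than the 1% expected by chance. Among named features, 304 of 348 values kept direction and side and 6 turned: without CCG and CGG CpGs, the regions on chromosomes 3 and 11 gave -0.751 and 0.130; without CpGs ranging over 40 points, those on chromosomes 3, 20 and 11 gave -0.111, -1.02 and 0.130; without CpGs at 10% or less in 1 animal and 90% or more in another, chromosome 3 gave -0.111. These settings remove CpGs from the regions. Same-numbered animals had correlations of -0.101, -0.121, 0.0892 and -0.0835, so they were not treated as pairs; the replicate block gave 293 CpGs, 1 region (another one, higher) and 0 windows. Not run were the 5-read minimum and the promoter, gene list and gene body results. At this depth 25.5% of simulated 20-point changes at single CpGs of middle level were recovered, beside other planted changes that loosen the adjusted threshold. Depth was not varied in the simulation.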

Other observations

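The test of haplotype blocks was set before its result was seen, and the remaining values here were chosen after the data were seen. By chromosome, CpG methylation was higher in injured animals on all 21 nuclear chromosomes measured, by 0.237 (chromosome 13) to 0.558 points (chromosome 12), and CA methylation was lower on all 21, with differences of -0.0629 (chromosome 19) to -0.0284 points (X). No chromosome passed the test (exact permutation tests, smallest adjusted p = 0.543 for CpG and 0.743 for CA, n = 4 per group), and the chromosomes share the same animals. CA methylation was uneven along the genome. Windows of 100 kb had 0.407% at the 5th and 2.63% at the 95th percentile, and the X chromosome had 0.932% ± 0.0981 in sham animals. Across 11301 windows, which are not independent replicates, CA and CpG levels rose together, with a Spearman correlation of 0.442 to 0.496 in single animals. With the windows sorted by CpG level into 5 equal groups, the lowest group (mean CpG level 13.8%) had a CA level of 0.792% ± 0.0683 (SD over 8 animals). The group with a mean CpG level of 71.0% had 1.69% ± 0.193 and the highest group (84.8%) had 1.65% ± 0.193. Of all windows, 85.2% were higher in sham 1, the animal with the highest CA level, than in TBI 1, the animal with the lowest.

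A set of whole regions differed widely between animals without regard to injury. Among 56661 autosomal regions with 5 or more CpGs, 193 had levels that ranged over 40 points, and in 111 of these at least 80% of the CpGs did so too. On chromosome 12 (40631084 to 40631199, 6 CpGs, at least 214 reads) sham 4 and sham 3 had 18.5 and 20.9%, TBI 1 and TBI 2 had 93.1 and 89.7%, and the other 4 animals had 48.1 to 55.6%. On chromosome 4 (177335615 to 177335797, 11 CpGs) sham 1 had 10.1% and sham 2 had 84.3%. On chromosome 1 (13504046 to 13504145, 16 CpGs) sham 3 and TBI 3 had 7.37 and 5.81% and TBI 2 had 74.1%. Each animal had at least 7082 reads there, against a median of 128 per region and animal. Several other regions between 13500338 and 13505429 on chromosome 1 had the same pattern, with TBI 2 highest and sham 3 and TBI 3 lowest. So did regions on chromosome 14. At 46834603 to 46834689, sham 3 and TBI 3 had 7.06 and 8.73% and TBI 2 had 79.1%. At 46702275 to 46702372 they had 20.9, 23.2 and 84.2%. Why both chromosomes shared the pattern, and why depth was high, was not tested. The 111 regions are therefore not independent loci. In 4 of them the groups differed at an unadjusted exact permutation p below 0.05, where 3.17 would be expected of 111 independent regions. Another 1616 regions with 5 or more CpGs had every animal between 35 and 65%, with a median SD of 5.17 points.

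Haplotype blocks, stretches of DNA inherited together in an outbred stock, are a candidate explanation for CpGs whose levels range widely between animals. The levels of 9196 such CpGs, chosen without regard to group, had a mean squared correlation of 0.278 for pairs under 10 kb apart, 0.237 from 10 to 100 kb, 0.197 from 100 kb to 1 Mb and 0.164 from 1 to 10 Mb, against 0.159 on different chromosomes. The excess under 100 kb was 0.0833, between the bounds of 0.05 and 0.1 set beforehand, so the test leaves this open. At CA cytosines, 10.9 of 10000 stood at 40% or more in 1 animal and at 5% or less in another, against 0.936 at CC and 1.97 at CT. Of the 2969 such cytosines of these 3 contexts together, the 751 with a widely ranging CpG within 10 kb had a mean squared correlation of 0.372 with it and of 0.139 with a random one.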
